A study of Homo sapiens with 6 samples.

How the data were processed

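RNA was sequenced from 6 samples of 5637, an established human bladder cancer cell line, of which 3 libraries were labelled siYTHDC1 and 3 were labelled siNC, the control group. The name siYTHDC1 was read as silencing of YTHDC1, which encodes a nuclear protein that binds N6-methyladenosine (m6A) in RNA. The labels speak of a transfection, an infection and a plasmid as well, so which reagent the cells received is unclear. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with a directional RNA kit. The deposited table holds raw read counts per Ensembl gene with 1 column per library, as whole numbers with a different total in each column. The genome build was hg38 per the submitters' processing notes. The aligner, the counting program, the annotation release and the strand setting of the counting are not given in the sources used here. Each column was assigned to a library by matching its name to the sample title, and 0 columns of the table were left unused. One part of the names of the siYTHDC1 columns is not explained by the labels.

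The table had 61860 genes. Gene symbols came from a table of Ensembl identifiers for 61757 of them and from GENCODE release 29 for a further 101, and 2 stayed without a name. Positions, exon structures, transcript lengths and GC content were taken from GENCODE release 29 on the same build, which holds 58308 of the genes. Of each gene named in the text, the share of exonic bases that lie under exons of other genes, and the share of its 75-base words that recur in transcripts of other genes, were computed from the same release, because reads from such stretches can be discarded or split by the counting. Shares under other exons count both strands unless stated. On the same strand they were 0% for SLC2A12, CCNE2, IER2 and ACTA2, 3.28% for SRSF2 and 8.03% for DDIT3. They were 24% for ZNF497, 42.3% for ALDOA, 51.6% for ITGB3 and 56.6% for SRSF1. Overlap on the other strand matters only if the counting ignored the strand. RefSeq accessions of 1 number series were taken as a mark of a predicted copy on an alternate scaffold; the alternate scaffolds themselves were not analysed here, so what the mark means for a gene was not checked.

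Differential expression was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the counts as deposited, with TMM scaling and the default filter on low counts, which kept 17372 genes. All 6 libraries entered 1 fit with the group as the only term. A gene was called when its p-value, adjusted by Benjamini and Hochberg over all genes tested, was under 0.05. Called genes are said to have risen or fallen in the libraries labelled siYTHDC1 relative to those labelled siNC. Log2 fold changes are given with standard errors (SE), and levels are TMM-scaled counts per 1000000 counts (CPM) with the SD over 3 libraries. RNF183 did not pass the filter and was added to the fit for its own value, beside an exact permutation test of its CPM. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

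Gene lists were fixed before the data were examined, as were the rule for named genes, the tests of genes and lists and the alternatives. They covered glucose transporters, glycolysis, the pentose phosphate and serine pathways, the TCA cycle, nuclear-encoded oxidative phosphorylation, lipid synthesis, hypoxia targets, endoplasmic reticulum (ER) stress, the ATF4 stress response, p53 targets, apoptosis, S phase, G2/M, interferon response, NF-κB targets and cytokines, immediate early genes, luminal, basal, epithelial and mesenchymal markers, m6A machinery, splicing and RNA processing, ribosomal proteins, replication histones, RNF ubiquitin ligases, nuclear lncRNAs with snoRNA hosts, and ZNF genes. These 27 lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, 2-sided, and adjusted over the 27 lists. Camera with an estimated correlation and fry were alternatives. Lists of fibroblast, immune and endothelial markers were counted and not set-tested, and the 13 protein genes of the mitochondrial genome were listed at 0 in each library.

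The named genes were the 3 in the series title; the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM, no overlap between the groups and a symbol other than a clone-type or LINC name; and up to 4 called members of each list with the largest changes and a mean of at least 1 CPM. Uncalled glucose transporters and glycolysis genes are given only as values. Genes outside this rule are marked in the text as chosen after their values were seen. Some genes that met the rule are not reported here. Genes of the Y chromosome and XIST were not reported.

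The other settings tried were median-ratio, upper-quartile and no scaling in edgeR, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of at least 1 CPM in at least 3 libraries, a term for the replicate number, and leaving out each library in turn. The edgeR step was tested on simulated counts for this comparison, drawn for the 17372 genes from the real means, library sizes and dispersions. Of these, 17037 passed the filter on low counts again and were tested. The edgeR step recovered 98% of 50 genes changed 4-fold, 88% of 50 changed 2-fold, 68% of 50 changed 1.5-fold and 44% of 50 changed 1.2-fold, and 4.49% of its calls were false. There 16837 genes were unchanged and genes were drawn independently, whereas in the data 8094 genes were not called. Only genes above a minimum mean count were changed. These rates therefore need not hold for the real calls. In a further simulation with the ER stress list shifted by 0.5 on the log2 scale, camera called that list and 0 of the other 26. Genes were again drawn independently and no gene outside that list was shifted. It therefore cannot show how often camera calls lists falsely when genes are correlated.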

Results

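The series measured gene expression in 5637 bladder cancer cells in 3 libraries labelled siYTHDC1 and 3 libraries labelled siNC. Its title names an axis of YTHDC1, GLUT3 (the protein of SLC2A3) and RNF183 in glucose metabolism, so the comparison asks how transcripts, those of glucose metabolism among them, differ when YTHDC1 is targeted. Total counts were 35607577, 34628360 and 34722602 in siNC replicates 1 to 3 and 34858457, 33223480 and 34104618 in siYTHDC1 replicates 1 to 3, and 24308 to 24470 genes had at least 1 count in a library. Pearson's r of log2 CPM across genes was 0.989 to 0.990 between libraries of 1 group and 0.972 to 0.974 between groups (genes are not independent replicates). The first principal component held 57.7% of the variance and separated the groups. Every pair of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of 3.76 to 5.85.

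The row of the targeted gene did not separate the groups. YTHDC1 (ENSG00000083896, 4:68310387-68350089 on hg38, up to 17 exons) had 50, 786 and 55 counts in siNC replicates 1 to 3 and 161, 18 and 14 counts in siYTHDC1 replicates 1 to 3. This is 8.60 ± 12.3 CPM (SD, n = 3) against 1.85 ± 2.39 CPM (SD, n = 3). The fitted log2 fold change was -2.20 ± 0.69 (SE), with an edgeR adjusted p of 0.00864. It rested on siNC replicate 2: without that library it was 0.31 (edgeR adjusted p = 0.691). Without siYTHDC1 replicate 2 it was -1.77 (edgeR adjusted p = 0.0666), and with limma-voom -1.83 (limma adjusted p = 0.0861). Over all alternatives its adjusted p ran from 4.66e-31 in edgeR without the low-count filter to 0.691. Since siYTHDC1 replicate 1 held more YTHDC1 counts than 2 of the 3 siNC libraries, groups are named here by their labels, and every direction given is that of the libraries labelled siYTHDC1 relative to those labelled siNC.

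**Figure D1:**
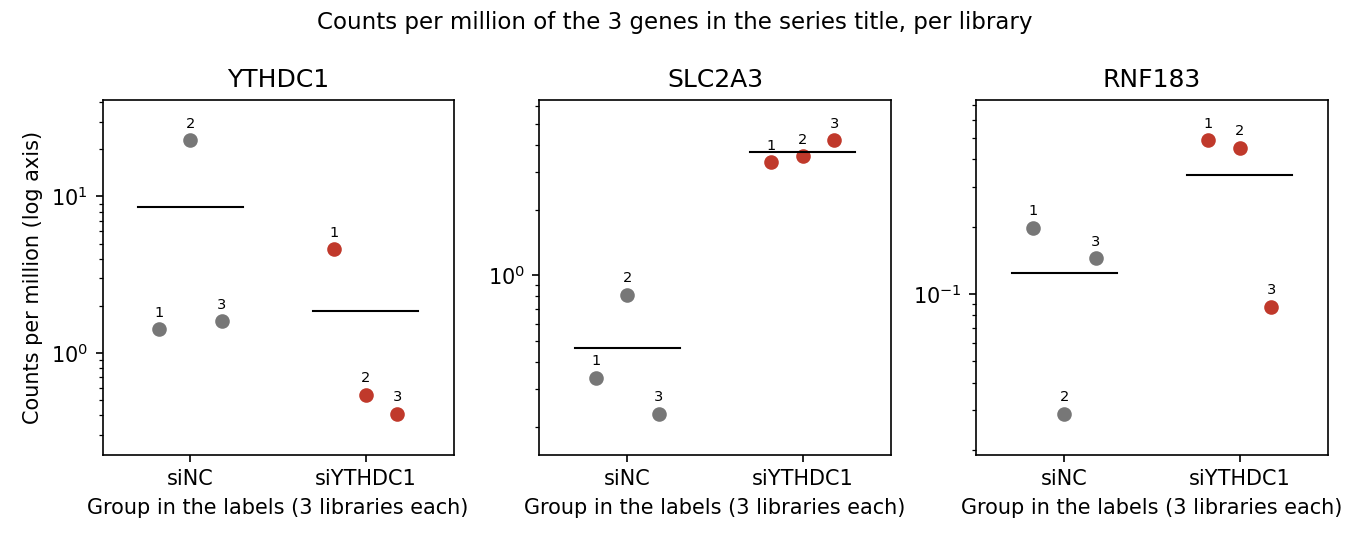
CPM (log axis) of YTHDC1, SLC2A3 and RNF183 in each library, with points numbered by replicate and lines at the group means. YTHDC1 and RNF183 overlapped between the groups, whereas the 3 siYTHDC1 libraries lay at 3.32 to 4.18 CPM of SLC2A3 and the 3 siNC libraries at 0.231 to 0.813.

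SLC2A3, which encodes the neuronal-type glucose transporter GLUT3, was 7.95-fold higher in the libraries labelled siYTHDC1, a size that rests on few siNC counts. Its row (ENSG00000059804, 12:7919230-7936275, up to 10 exons) had 12, 28 and 8 counts in the siNC libraries and 116, 118 and 143 counts in the siYTHDC1 libraries. The level went from 0.461 ± 0.309 CPM to 3.68 ± 0.446 CPM (SD, n = 3 each), a log2 fold change of 2.99 ± 0.33 (SE; edgeR adjusted p = 1.66e-08), which ran from 2.67 without siNC replicate 3 to 3.67 without siNC replicate 2 when 1 library was left out. Of the 75-base words of SLC2A3, 8.11% recur in its paralog SLC2A14, which had 1 count in the siNC libraries together and 0 in the siYTHDC1 libraries. RNF183, a RING-type ubiquitin ligase (ENSG00000165188, 9:113297093-113303376), was near the floor, with 7, 1 and 5 counts in the siNC libraries and 17, 15 and 3 counts in the siYTHDC1 libraries. The groups were not told apart at this depth: the log2 fold change was 1.43 ± 0.76 (SE; edgeR adjusted p = 0.110), and an exact 2-sided permutation test of CPM gave p = 0.3, where 3 against 3 cannot go below 0.1. Without siYTHDC1 replicate 3 the RNF183 value was 1.88 (edgeR adjusted p = 0.0432, the lowest of a range up to 0.347 over the alternatives).

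Among the glucose transporters, 3 of 10 tested members rose and 4 fell, the same counts as when adjusted over the list alone. The rises were SLC2A3, SLC2A13 (0.62 ± 0.11, SE), a proton-coupled myo-inositol transporter, and SLC50A1 (0.59 ± 0.06). SLC2A9, a urate transporter, fell by 1.06 on the log2 scale. SLC2A1, the broadly expressed transporter GLUT1, was chosen after its values were seen: it was far more abundant than SLC2A3 and fell from 360 ± 2.21 to 270 ± 10.6 CPM (SD, n = 3 each; log2 fold change -0.42 ± 0.03). The other falls, named after their values were seen, were SLC2A6 and SLC2A12. SLC2A12 has 38.9% of its exonic bases under exons of other genes, and its call was lost in 3 of the 6 fits that left out 1 library (edgeR adjusted p from 0.000338 to 0.0882, the highest without siYTHDC1 replicate 1). The 3 uncalled members had log2 fold changes of 0.12 for SLC2A10, -0.32 for SLC2A4 and -0.05 for SLC2A8, and SLC2A10 passed in 1 such fit (edgeR adjusted p = 0.0479, without siYTHDC1 replicate 1, the others reaching 0.347). The list did not pass camera (adjusted p = 0.736), its mean log2 fold change (0.19) being opposite in sign to its median (-0.11) and to the camera direction.

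Of 29 glycolysis genes, 5 rose and 12 fell (5 and 13 when adjusted over the list alone), and the list did not pass camera (adjusted p = 0.0841, median log2 fold change -0.08). LDHA, the lactate dehydrogenase subunit that favours lactate formation, fell from 1619 ± 31.9 to 971 ± 10.6 CPM (SD, n = 3 each). The lactate transporter gene SLC16A1 fell by 1.27 on the log2 scale and PDK1, a kinase that inhibits pyruvate dehydrogenase, by 0.64. The risen members were the hexokinase genes HK1, HK2 and HKDC1 and the phosphofructokinase genes PFKL and PFKM, with log2 fold changes from 0.19 for PFKM to 0.75 for HKDC1. All but HKDC1 of these 5 were chosen after their values were seen. Most of the 12 falls are not named here, whereas all 5 rises are, so the named genes do not show the balance of the list. The 12 uncalled members lay between -0.91 for ALDOC and 0.26 for ALDOA. ALDOC was scarce and its groups overlapped, with 23, 17 and 43 counts in the siNC libraries and 16, 22 and 5 in the siYTHDC1 libraries. ALDOA is uncertain because 53.5% of its exonic bases lie under exons of other genes, and it passed in 2 of the 6 fits that left out 1 library (edgeR adjusted p = 0.0312 without siNC replicate 3 and 0.0433 without siYTHDC1 replicate 1, the others reaching 0.539).

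Across all genes, 9278 of 17372 were called (53.4%), of which 4576 rose and 4702 fell. Most changes were small: 5501 calls (59.3%) were under 0.5 on the log2 scale, and 1363 were at least 1 in size, with 869 rises and 494 falls. The groups did not overlap in 10301 genes (59.3%), where chance gives 10%. Of 13472 protein-coding genes 28.6% rose and 31.7% fell, while of 2261 lncRNA genes 22.2% rose and 10.5% fell. The common biological coefficient of variation between replicates was 0.056.

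Among called genes with a mean of at least 5 CPM and no overlap between the groups, the largest rise was in ANGPTL4, an inhibitor of lipoprotein lipase, from 0.728 ± 0.195 to 9.28 ± 0.714 CPM (SD, n = 3 each; 12.7-fold). SERPINB7 (2.78 ± 0.12, SE), WFIKKN1 (2.58 ± 0.15), the adrenomedullin-family peptide gene ADM2 (2.52 ± 0.10), the transcription factor gene CREB5 (2.42 ± 0.14), the asparagine synthetase gene ASNS (2.42 ± 0.14), GOLGA7B (2.42 ± 0.05) and the secreted pattern-recognition gene PTX3 (2.38 ± 0.10) followed on the log2 scale. PLAAT4, a phospholipase and acyltransferase gene, had the largest fall among such genes, being 7.21-fold lower (log2 fold change -2.85 ± 0.18, SE). LSP1 went from 8.35 ± 1.18 to 2.08 ± 0.305 CPM (SD, n = 3 each). METTL7A (-2.09 ± 0.16, SE), the apolipoprotein L gene APOL3 (-2.03 ± 0.17), the p38 kinase activator gene MAP2K6 (-1.98 ± 0.10) and the choline dehydrogenase gene CHDH (-1.86 ± 0.17) fell by similar amounts. S100A8, a calcium-binding alarmin, fell from 519 ± 13.0 to 139 ± 6.71 CPM, and LBR, the lamin B receptor, from 227 ± 5.80 to 63.0 ± 1.46 CPM (SD, n = 3 each). The edgeR adjusted p of these 16 genes was at most 3.03e-10, for CHDH. ASNS is uncertain in size, since 44.6% of its exonic bases are shared with other genes on the same strand.

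Camera called 12 of the 27 lists, 8 higher and 4 lower. With an estimated correlation 0 of the 27 passed after adjustment and 8 had an unadjusted p under 0.05, whereas fry, which asks whether the genes of a list move 1 way on balance without comparing them with other genes, called 23.

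**Figure D2:**
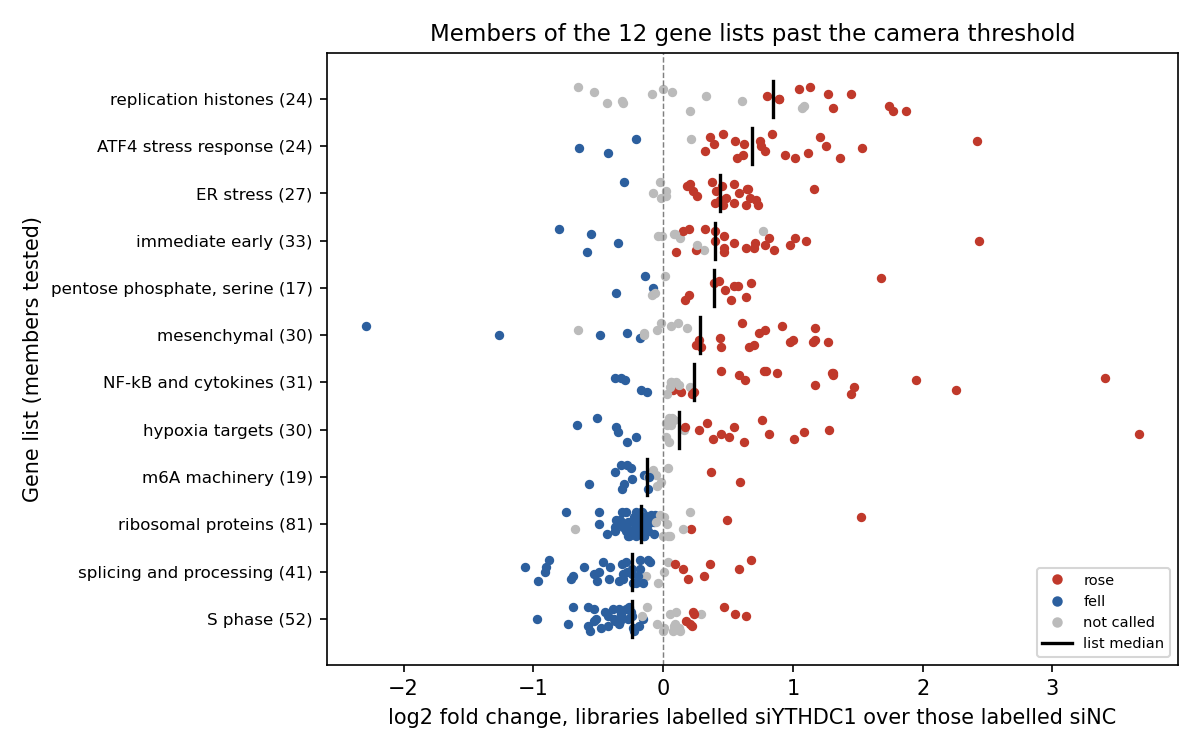
Log2 fold change (x axis) of each tested member of the 12 gene lists that passed camera (y axis, members tested in parentheses), coloured by the edgeR call, with a black line at each list's median. Medians ran from -0.24 in the S phase list to 0.84 in the replication histones.

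Genes of the ATF4 stress response, which cells engage on amino acid shortage, rose in 20 of 24 members and fell in 3 (21 and 3 when adjusted over the list alone), with a median log2 fold change of 0.68 (camera adjusted p = 3.25e-07; adjusted p = 0.0935 with an estimated correlation). ASNS, the cytokine gene GDF15 (1.53 ± 0.06, SE), the pro-apoptotic factor gene DDIT3 (1.36 ± 0.15), which encodes CHOP, and the cystathionine gamma-lyase gene CTH (1.26 ± 0.08) rose. CEBPB, SLC3A2 and SLC7A5, named after their values were seen, fell, and the last pair encode the subunits of an amino acid transporter. DDIT3 has 39.6% of its exonic bases under exons of other genes. Genes of the ER stress response rose in 21 of 27 members, and 1, DERL2, named after its values were seen, fell (the same when adjusted over the list alone; median 0.44; camera adjusted p = 2.19e-06; adjusted p = 0.105 with an estimated correlation). HERPUD1 (1.16 ± 0.05), a component of ER-associated degradation, the chaperone gene HSP90B1 (0.73 ± 0.02), XBP1 (0.72 ± 0.03) and ERN1 (0.67 ± 0.06), which encodes the sensor that splices XBP1 mRNA, rose.

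In the pentose phosphate and serine list 11 of 17 members rose and 3 fell (the same when adjusted over the list alone; median 0.40; camera adjusted p = 0.00918; adjusted p = 0.415 with an estimated correlation). Its 3 enzymes of serine synthesis rose, PSAT1 from 50.1 ± 0.755 to 160 ± 4.77 CPM (SD, n = 3 each), PHGDH by 0.68 ± 0.03 and PSPH by 0.64 ± 0.06 on the log2 scale (SE), as did the mitochondrial folate enzyme gene MTHFD1L (0.58 ± 0.04). The fallen members were MTHFD1, PGD and TALDO1, the last pair being pentose phosphate enzymes, all named after their values were seen. The PGD call was lost in 4 of the 6 fits that left out 1 library (edgeR adjusted p from 0.0243 to 0.177, the highest without siNC replicate 2).

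NF-κB targets and cytokines rose in 19 of 31 members and fell in 5 (the same when adjusted over the list alone; median 0.24; camera adjusted p = 2.2e-05; adjusted p = 0.105 with an estimated correlation). TNFRSF9, a costimulatory receptor, rose by 3.41 ± 0.19 (SE), the growth factor gene CSF2 by 2.26 ± 0.11 and the chemokine gene CCL20 by 1.95 ± 0.09 on the log2 scale. SOD2, the mitochondrial superoxide dismutase, rose from 457 ± 2.56 to 1268 ± 25.3 CPM (SD, n = 3 each). The 5 falls, named after their values were seen, were CXCL2, CXCL3, IL23A, TNFAIP2 and ZC3H12A, of which ZC3H12A encodes an RNase that degrades cytokine mRNAs. In fits that left out 1 library, CXCL2 lost its call in 4 of 6 (edgeR adjusted p from 0.0243 to 0.252, the highest without siNC replicate 1) and IL23A in 3 of 6 (0.0203 to 0.146, the highest without siYTHDC1 replicate 3). Immediate early genes rose in 21 of 33 members and fell in 4 (the same when adjusted over the list alone; median 0.40; camera adjusted p = 1.5e-04; adjusted p = 0.105 with an estimated correlation). CCN1 (1.10 ± 0.08), the phosphatase gene DUSP5 (1.01 ± 0.06), KLF4 (0.98 ± 0.06) and SPRY4 (0.85 ± 0.07) rose, DUSP5 and SPRY4 encoding feedback inhibitors of MAP kinase signalling. IER2, JUNB, JUND and KLF2, named after their values were seen, fell, IER2 with 30.8% of its exonic bases under exons of other genes.

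Hypoxia targets rose in 14 of 30 members and fell in 6 (the same when adjusted over the list alone; median 0.12; camera adjusted p = 0.0132; adjusted p = 0.115 with an estimated correlation). Besides ANGPTL4, the oxidoreductase gene ERO1A (1.28 ± 0.04, SE), STC2 (1.09 ± 0.04) and the angiogenic factor gene VEGFA (1.01 ± 0.04) rose. Only rises of this list are named here and its 6 falls are not, so the named genes do not show its balance. Mesenchymal markers rose in 17 of 30 members and fell in 5 (the same when adjusted over the list alone; median 0.29; camera adjusted p = 0.00361; adjusted p = 0.297 with an estimated correlation). The smooth muscle actin gene ACTA2 (1.27 ± 0.21), the activin subunit gene INHBA (1.17 ± 0.03) and the matrix metalloproteinase gene MMP10 (1.17 ± 0.12) rose. ITGB3 fell by 1.26 on the log2 scale. Of the exonic bases of ITGB3 51.6%, and of those of ACTA2 30.1%, lie under exons of other genes. The other falls, named after their values were seen, were CDH2, FN1, SPARC and TWIST1, each of them a widely used mesenchymal marker. SPARC was scarce, with a mean under 1 CPM, so the size of its fall is uncertain (log2 fold change -2.29 in edgeR and -3.15 with limma-voom). TWIST1 lost its call in 4 of the 6 fits that left out 1 library (edgeR adjusted p from 0.0198 to 0.134, the highest without siNC replicate 2).

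Ribosomal protein genes fell in 67 of 81 members and rose in 3 (68 and 3 when adjusted over the list alone), by a small median of -0.17 on the log2 scale (camera adjusted p = 1.58e-07; adjusted p = 0.105 with an estimated correlation). RPS26 fell from 298 ± 4.38 to 177 ± 6.95 CPM (SD, n = 3 each), and RPL22 fell by 0.49 on the log2 scale. RPL26L1, a paralog of RPL26, rose by 0.49 ± 0.07 (SE), as did RPL11 and RPL3L, which were named after their values were seen. RPL3L was scarce and lost its call in 5 of the 6 fits that left out 1 library (edgeR adjusted p from 0.0237 to 0.175, the highest without siNC replicate 2). Many of these genes have processed pseudogenes, and how the counting treated their shared reads is not given in the sources used here.

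Splicing and RNA processing genes, among them known partners of YTHDC1, fell in 30 of 41 members and rose in 7 (the same when adjusted over the list alone; median -0.24; camera adjusted p = 6.32e-05; adjusted p = 0.0966 with an estimated correlation). The largest changes were all in serine/arginine-rich splicing factors: SRSF1 fell from 112 ± 3.08 to 53.5 ± 1.36 CPM, SRSF6 from 135 ± 5.69 to 69.3 ± 3.68 CPM, SRSF2 from 231 ± 7.88 to 123 ± 1.28 CPM and SRSF3 from 367 ± 1.89 to 197 ± 3.40 CPM (SD, n = 3 each). SRSF1 has 60.7% and SRSF2 36.7% of its exonic bases under exons of other genes. The m6A machinery, in which YTHDC1 itself was not counted, fell in 11 of 19 members and rose in 2 (the same when adjusted over the list alone; median -0.12; camera adjusted p = 0.0272; adjusted p = 0.142 with an estimated correlation). The cytoplasmic m6A reader genes YTHDF3 and YTHDF1 fell by 0.57 and 0.37 on the log2 scale, while RBM15 (0.59 ± 0.05, SE), a subunit of the methyltransferase complex, and the reader gene IGF2BP2 (0.37 ± 0.04) rose.

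Genes of S phase fell in 31 of 52 members and rose in 8 (31 and 9 when adjusted over the list alone; median -0.24; camera adjusted p = 0.0014; adjusted p = 0.142 with an estimated correlation). UHRF1, needed to maintain DNA methylation, fell from 219 ± 3.26 to 112 ± 6.83 CPM (SD, n = 3 each), the cyclin gene CCNE2 fell by 0.73 and the helicase gene HELLS by 0.70 on the log2 scale, and E2F8 rose by 0.64 ± 0.08 (SE). CCNE2 has 37.1% of its exonic bases under exons of other genes. Replication histones rose in 11 of 24 members and fell in 0 (the same when adjusted over the list alone; median 0.84; camera adjusted p = 0.00862; adjusted p = 0.115 with an estimated correlation). Their transcripts were scarce: H2BC5 went from 4.92 ± 0.346 to 13.4 ± 0.535 CPM (SD, n = 3 each), and H2AC8, H2BC11 and H2BC4 had log2 fold changes of 1.87 ± 0.44, 1.77 ± 0.33 and 1.74 ± 0.34 (SE) from siNC levels under 1 CPM. The H2AC8 value ran from 1.498 without siNC replicate 2 to 2.603 without siNC replicate 3 when 1 library was left out, its siNC counts being 12, 6 and 27.

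Genes of respiration and lipid synthesis moved in both directions, and none of these 3 lists passed camera. Of 72 nuclear-encoded oxidative phosphorylation genes 11 rose and 27 fell (camera adjusted p = 0.122), ATP5F1A falling by 0.87 and CYCS, the cytochrome c gene, rising by 0.66 ± 0.04 (SE) on the log2 scale. Of 29 TCA cycle genes 9 rose and 11 fell (camera adjusted p = 0.88), with a mean of 0.016 opposite in sign to the median of -0.033 and to the camera direction. PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, rose by 1.38 ± 0.05 and SDHB by 0.64 ± 0.05, while IDH3B and SUCLG2 fell by 0.52 and 0.49. In lipid synthesis 12 of 33 genes rose and 16 fell (camera adjusted p = 0.455; 12 and 17 when adjusted over the list alone). The counts of the oxidative phosphorylation and TCA lists were the same when adjusted over the list alone.

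Of 58 G2/M genes 13 rose and 24 fell (camera adjusted p = 0.114), among them LBR and CKAP2L, which fell by 1.85 and 0.58 on the log2 scale. Of 30 RNF ubiquitin ligase genes 10 rose and 8 fell (camera adjusted p = 0.818), with a mean of 0.054 opposite in sign to the median of -0.019; RNF144B rose by 0.64 ± 0.10 (SE) and RNF115 fell by 0.56. The counts of both lists were the same when adjusted over the list alone. Of 455 ZNF genes 107 rose and 104 fell (102 and 100 when adjusted over the list alone; camera adjusted p = 0.843), and the largest changes were the falls of ZNF132 (-2.33 ± 0.39) and ZNF497 (-1.78 ± 0.27). ZNF497 has 45.3% of its exonic bases under exons of other genes. Markers of other cell types were few above the filter. Of 4 fibroblast markers THY1 and COL1A1 rose, by 0.30 ± 0.06 and 0.19 ± 0.04; of 2 immune markers CD14 fell by 0.37; and of 4 endothelial markers ESAM rose by 0.98 ± 0.25 and VWF fell by 0.98 (the same counts when adjusted over the list alone). In fits that left out 1 library, CD14 lost its call in 3 of 6 (edgeR adjusted p from 0.0137 to 0.171, the highest without siYTHDC1 replicate 2) and VWF in 4 of 6 (0.00185 to 0.236, the highest without siNC replicate 1).

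SLC16A1, PCK2, SLC2A6, RPL3L and IFI27 carry a RefSeq accession of the number series that YTHDC1 also carries, taken here as a mark of a predicted copy on an alternate scaffold. The marked genes differed in how far their replicates scattered. IFI27, an interferon response gene, had 45, 36 and 11 counts in the siNC libraries and 153, 175 and 58 in the siYTHDC1 libraries, and RPL3L had 12, 1 and 8 against 23, 16 and 21. The others were tighter: SLC2A6 was at 88.7 ± 5.24 and 65.6 ± 1.13 CPM, SLC16A1 at 239 ± 3.98 and 98.7 ± 1.28 CPM and PCK2 at 51.6 ± 3.41 and 134 ± 0.442 CPM in the libraries labelled siNC and siYTHDC1 (SD, n = 3 each).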

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

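The alternatives here were planned before the data were examined. The number of genes called lay between 8533 and 9308 in the 14 alternatives, against 9278, and 94.6% or more of the called genes were also called in each alternative that used all 6 libraries and 89.0% or more in each fit that left out 1 library. No scaling moved the median log2 fold change of all genes by more than 0.011, and the share of calls that rose stayed between 48.6% and 51.0%. The count of calls of at least 1 on the log2 scale fell from 1363 to 885 with the filter of at least 1 CPM in at least 3 libraries, which tested 14460 genes in place of 17372 and so held fewer scarce genes; elsewhere it was 1297 to 1561. The rise of SLC2A3 kept its direction and its side of the threshold in each alternative, with log2 fold changes of 2.67 to 3.67 when 1 library was left out.

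The YTHDC1 change did not hold. It ranged from -4.17 without siYTHDC1 replicate 1 to 0.31 without siNC replicate 2, where its direction turned because that library held 786 of the 891 YTHDC1 counts of the siNC group. It was -1.77 without siYTHDC1 replicate 2 and -1.83 with limma-voom, both no longer past the threshold, and DESeq2 gave it no adjusted p. The RNF183 change ranged from 0.98 without siNC replicate 2 to 1.93 without siNC replicate 1 and was past the threshold only without siYTHDC1 replicate 3, at 1.88, the library with the fewest RNF183 counts of its group. RNF183 had 48 counts in the 6 libraries together, and whether depth or the spread between replicates limits this comparison was not tested.

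Of the 12 lists called by camera, 0 passed with an estimated correlation and 23 of the 27 lists passed with fry. In the 11 other settings tried for the lists the 12 calls held (camera was not run with upper-quartile scaling, DESeq2 or limma-voom); glycolysis, oxidative phosphorylation and G2/M were also called without the low-count filter, and G2/M without siYTHDC1 replicate 3, and the cause was not tested. The same-numbered libraries of the 2 groups did not deviate together (correlations across genes of 0.005, -0.007 and -0.017), so the numbers were not taken to pair the libraries. A term for the replicate number gave 9227 calls with 4532 rises and 4695 falls, a YTHDC1 change of -1.68 and 12 called lists, and of the 143 named genes besides the 3 of the series title it ended only the VWF call. Of those 143 genes 0 turned direction in any alternative. Many of them were named for large changes in these same data, so a kept direction was largely set by that choice. Over the 8 alternatives with 6 libraries 12 of 1141 gene values lost their call. Over the fits that left out 1 library 31 of 858 lost it and 3 gained it.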

Other observations

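The test of alternate scaffolds for YTHDC1 and the test of SLC2A14 counts for SLC2A3 were chosen after the results they bear on were seen. The cell identity lists, not described so far, moved in both directions. Of 18 luminal urothelial markers 3 rose and 8 fell (the same when adjusted over the list alone; camera adjusted p = 0.14). The keratin genes KRT7 and KRT8 fell from 1801 ± 23.2 to 874 ± 22.1 CPM and from 1993 ± 20.5 to 1044 ± 10.6 CPM in the libraries labelled siYTHDC1 (SD, n = 3 each), while PPARG, a transcription factor of luminal cells, rose by 0.98 ± 0.04 (SE) and TMPRSS2 by 0.91 ± 0.06 on the log2 scale. Of 27 basal and squamous markers 12 rose and 11 fell (the same when adjusted over the list alone; camera adjusted p = 0.88). SPRR1B, a precursor of the cornified envelope, rose by 2.68 ± 0.29 (SE), while KRT5 fell from 1548 ± 12.9 to 655 ± 5.55 CPM (SD, n = 3 each) and S100A8 also fell. Of 32 epithelial adhesion genes 12 rose and 10 fell (the same when adjusted over the list alone; camera adjusted p = 0.749), with CLDN3 and KRT80 falling by 1.19 and 0.68 and PKP2 and SPINT1 rising by 0.69 ± 0.07 and 0.61 ± 0.03 (SE). The 10 most abundant genes took 4.36% to 4.43% of the counts in the siNC libraries and 3.56% to 3.6% in the siYTHDC1 libraries.

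Antiviral and cell death genes were split as well. Of 47 interferon response genes 12 rose and 20 fell (13 and 20 when adjusted over the list alone; camera adjusted p = 0.269). OASL, CMPK2 and TRIM22 fell by 2.33, 2.10 and 1.51 on the log2 scale, whereas IFI27 went from 0.878 ± 0.498 to 3.78 ± 1.85 CPM (SD, n = 3 each), a gene that carries the same mark of an alternate scaffold as YTHDC1. Of 27 p53 targets 13 rose and 8 fell (the same when adjusted over the list alone; camera adjusted p = 0.406). CDKN1A, the cell cycle inhibitor p21, fell from 412 ± 4.47 to 237 ± 8.31 CPM (SD, n = 3 each), while SPATA18, PLK3 and the pro-apoptotic gene BBC3 rose by 0.93 ± 0.16, 0.92 ± 0.07 and 0.80 ± 0.08 (SE). Of 29 apoptosis genes 9 rose and 11 fell (9 and 12 when adjusted over the list alone; camera adjusted p = 0.917), with a median of -0.025 opposite in sign to the mean of 0.091 and to the camera direction. The anti-apoptotic genes BCL2A1 and BCL2L2 rose by 1.73 ± 0.12 and 1.15 ± 0.05 (SE), and the pro-apoptotic gene HRK rose by 1.49 ± 0.23. Of 32 nuclear lncRNAs and snoRNA hosts 12 rose and 8 fell (the same when adjusted over the list alone; camera adjusted p = 0.485). SNHG14 and NEAT1, the scaffold RNA of paraspeckles, fell by 1.33 and 1.11, while SNHG3 rose by 1.04 ± 0.08 (SE). H19 fell by 1.14, but its siYTHDC1 libraries held 44, 41 and 227 counts. Its log2 fold change was -2.43 without siYTHDC1 replicate 3 and -0.77 without replicate 1 or 2 of that group, so its size is uncertain, and the call was lost without siYTHDC1 replicate 2 (edgeR adjusted p = 0.0622) and with DESeq2 (adjusted p = 0.226), the highest of a range from 2.54e-11 over the alternatives.

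The YTHDC1 counts scattered between replicates far more than those of other genes, with a coefficient of variation beyond sampling noise of 1.43 against a median of 0.061. This was the rank 8 among genes with a symbol in RefSeq and a mean of at least 50 counts. For each gene the larger of the values of the 2 groups was taken, on unscaled counts. The comparison of scattering genes below uses the same genes and measure. Against reads shared with another annotated gene, 0% of the 75-base words of YTHDC1 occur in other transcripts. Against a wrong label of a single library, each library placed on an axis from siNC to siYTHDC1 with genes called without it lay within 0.182 of its own group's mean (0 to 1 scale). An exchange of the whole groups would leave these distances unchanged, so the axis cannot decide on that. On that axis siNC replicate 2 differed from replicates 1 and 3 by 0.0046. The axis leaves out YTHDC1 and need not follow its level, so this cannot decide on a true difference in YTHDC1 between the siNC cultures. A candidate explanation is that reads were split or discarded between YTHDC1 and a copy of its locus on an alternate scaffold: of 66 other genes that scatter by at least 0.5, 27.3% carry an accession of the series taken as a mark of an alternate scaffold, as YTHDC1 does, against 1.89% of 13007 other genes (Fisher's exact test, odds ratio 19.4, 95% interval 10.5 to 34.6, p = 5.03e-16). Most marked genes did not scatter so far: 246 of them lay under 0.5 and 18 did not, YTHDC1 left out. The comparison rests on that mark, since the scaffolds themselves were not analysed here, and why single libraries would differ in that split was not tested. Fisher's test also takes genes as independent, which they need not be, so its interval may be too narrow and its p too small. Until it is known how the reads were counted, the YTHDC1 row may say little about the extent of silencing in these libraries, and silencing itself stays untested.

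The ATF4 and ER stress lists rose and the splicing list fell with camera at the preset correlation, calls that were lost with an estimated correlation (adjusted p = 0.0935, 0.105 and 0.0966). A bias by GC content or transcript length is argued against, since after a smooth trend on both was removed each of the 3 list medians kept at least 90.2% of its size (0.68 to 0.67, 0.44 to 0.40 and -0.24 to -0.31). Single members do not carry the lists either, as the inner quartiles lay at 0.38, 0.19 and -0.10, the smallest being 0.103 from 0 on the list's side. A response of the cells to the loss of YTHDC1, or to the reagent apart from its target, may produce such changes; both stay open as hypotheses and neither was tested, since the labels give 1 silencing group and the YTHDC1 row is not readable as a check.

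SLC2A3 counts rose by 329 between the groups. Reads moved from the paralog SLC2A14 are argued against, as SLC2A14 held 1 count in the siNC libraries, 0.304% of that gain. A biological difference between the groups as labelled may remain as a hypothesis, and no other explanation was tested.

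YTHDC1 acts in the nucleus on splicing and export, so a further hypothesis was that genes with a longer genomic span fell more than short ones. The data went the other way: Spearman's rho across protein-coding genes between log2 fold change and span was 0.037, 0.086 and 0.11 in genes of low, middle and high mean expression (3 groups of equal size; genes are not independent replicates). In 5 groups of equal size by span, the group of the shortest genes, with a median span of 5.8 kb, had a median log2 fold change of -0.085, and that of the longest, with a median span of 165 kb, had 0.012.

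Of the 10 splits of the 6 libraries into 3 and 3, 1, the labelled one, gave as many as 9278 calls. The highest of the other 9 was 0 genes called with edgeR, where 142 to 175 genes had an unadjusted p under 0.05 against 10094 in the labelled split. Each of the other 9 splits mixes libraries of both labels in both groups, so the difference between the labels adds to the spread within groups. Their 0 calls were thus largely set in advance and do not measure chance. With 10 splits a share under 0.05 cannot be reached either.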
